A study of Mus musculus with 15 samples.

How the data were processed

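4C-seq was run for 5 viewpoints in E14 mouse embryonic stem cells (2 libraries per viewpoint) and in MEF (1 library per viewpoint), 15 libraries in all. Groups and the E14 replicate numbers were taken from the sample titles. The source and strain labels of the libraries titled MEF name E14 and its strain, so these libraries are called MEF by title only. Per the labels' protocols, chromatin was first cut with HindIII (EcoRI for CRE140), ligated, cut again with DpnII, NlaIII or CviQI and religated. From 3.2 µg of template per viewpoint an inverse PCR was run, smears of 200 to 600 bp were cut from a gel and sequenced on a MiSeq, and interactions were identified with r3Cseq. Per the submitters' processing notes, cutadapt, STAR and the mm9 build were used. Versions, mapping settings and filters are not given in the sources used here. The titles mark the E14 replicates BR, a common short form of biological replicate that the labels do not spell out, and no label names separate cultures. P-values measure the spread between these libraries only.

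The authors deposited 1 table per library with read counts per restriction fragment, a column headed RPMs, p-values and q-values. Per the file headers the counts are reads per fragment, and every file lists fragments down to 1 read, so a fragment that is not listed was taken as 0. The deposited RPMs column rises with the counts but is not proportional to them and its sums differ between libraries. It was treated as the authors' signal and not used for comparisons. CPM of fragments were computed from the counts and the library's total. The p-values and q-values are the authors', per library, and were used only to count called fragments. No molecular identifiers are named, so PCR copies are counted as reads. In every library, most pairs of touching fragments with at least 20 reads each had equal counts (68.7% to 91.2% of pairs). Keeping 1 fragment of each equal pair removes 23.6% to 31.2% of the reads.

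The viewpoint was located from the data, as primer positions are not given in the sources used here. The rule set before the data were examined took the chromosome with the most reads, scaled by library total, over the 3 libraries and on it the fragment with the most. For Oct4DE this gave an isolated fragment at 6269431 to 6273191 on chromosome 17 with few fragments around it. After the data were seen, a step was added that first takes the 1 Mb window (moved in steps of 500 kb) with the most distinct fragments. It changed the viewpoint fragment of Oct4DE only, and results under the first rule are given with the alternatives. Bins of 20 kb ran outward from 10 kb on each side of the middle of the viewpoint fragment, up to 1 Mb, and a fragment belonged to the bin that held its middle. Bins with at least 10 reads in at least 1 library were tested, 91 to 98 per viewpoint.

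Reads per bin were compared with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), by TMM normalisation, glmQLFit and glmQLFTest, 2 E14 libraries against 1 MEF library, each viewpoint fitted alone, with Benjamini-Hochberg adjustment over the bins of a viewpoint and a threshold of 0.05. The fit has 1 residual degree of freedom per bin, moderated over bins. Standard errors are the log2 change divided by the square root of F. CPM of bins are relative to the TMM-scaled reads in the tested bins. Where every library of a group had 0 reads, a fold is a lower bound against 3 reads in each library of that group. Where 1 E14 library had 0 reads, folds are given against each E14 library alone. With 1 to 3 reads it has an exact Poisson 95% interval of that count. The text names, for each viewpoint, up to 5 bins per direction with the largest change among those past the threshold with both E14 libraries on the same side of MEF, and cis fragments outside 10 kb with the smallest of the larger q of the E14 libraries. Any other bin is said to be chosen after its values were seen. Measures with 1 value per library were compared over the 5 viewpoints by an exact two-sided sign-flip permutation test of the E14 mean minus MEF, with 32 sign patterns and a smallest p of 0.062. The test takes the viewpoints as independent, and the sample titles do not say whether they were read from the same chromatin. The decay slope was fitted over 8 distance bands of equal log width, leaving out a band in which a library had 0 reads. This left 7 bands for the CRE111 MEF library and 8 for the others. Agreement used Spearman's rho and Pearson's r on log2(CPM + 1).

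Totals of 975602 to 2456752 reads mean that 3 reads, the limit a count of 0 allows, are 0.000122% to 0.000308% of a library. Intervals and floors cover counting error of reads only. They do not cover fragments that a library with few distinct fragments missed, so a fold given as at least a value does not bound a difference in contacts. The mean number of reads per listed fragment was 16.6 to 64.2 in E14 and 139 to 309 in MEF, so the number of distinct fragments, not of reads, limits MEF. Alternatives fixed beforehand were other scalings, the DESeq2 1.42.0 Wald test, other filters, bin widths, windows and distances left out, each fragment counted once, reads limited to the 95th percentile of cis fragments, E14 thinned to the MEF reads, a stricter q-value, other overlap rules and leaving out each E14 library. The fit was tested on simulated data, with counts drawn from the real means and library sizes of each viewpoint's 91 to 98 bins, 20 bins changed and 50 draws per fold. With no change, at most 0.25% of bins were called (the Oct4DE comparison), but these counts do not model the few distinct fragments of the MEF libraries. After the results were seen, the MEF library of each viewpoint was therefore also replaced by 100 substitutes. Each took as many fragments within 1 Mb as MEF had, drawn from the E14 fragments by their share of reads, and the MEF read values in random order. The reads on a drawn fragment therefore do not follow its reads in E14, which can lower the agreement of a substitute with E14. Its fragments come from the same libraries it is compared with, which can raise that agreement. The rank correlation between libraries was recomputed at all 5 viewpoints, and bins were tested at the 3 with calls, where the median number called was 37 at CRE132, 36 at Oct4DE and 0 at CRE140. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the rest.

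The gene table used here is of GRCm38 and the files are on mm9, so its coordinates were not used. A planned test of 5 gene lists against contacts on other chromosomes was not run, as it needs gene positions on the build of the files.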

Results

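The series measured chromatin contacts by 4C-seq, an assay in which crosslinked chromatin is cut, ligated, cut and circularised again, so that inverse PCR from 1 chosen site (the viewpoint) reads out the fragments ligated to it. The viewpoints were 5 elements titled CRE111, CRE18, CRE132, CRE140 and Oct4DE, from a series on enhancers in pluripotent stem cells. Oct4 is Pou5f1, a transcription factor that holds embryonic stem cells in the pluripotent state. Each element was profiled in E14, a mouse embryonic stem cell line, with 2 libraries, and in MEF, the usual abbreviation for mouse embryonic fibroblasts, with 1 library. The comparison addresses whether an element's contacts differ between the cell types. Chromatin was fixed in 1% formaldehyde for 10 min. The 15 libraries held 975602 to 2456752 reads. The 10 E14 libraries spread them over 24676 to 134294 restriction fragments and the 5 MEF libraries over 6205 to 10029.

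The primer positions are not given in the sources used here, so each viewpoint was placed on mm9 by its reads, and every distance below is from the fragment so chosen. On the chromosome with the most reads, the fragment with the most, scaled by library total, lay on chromosome 3 at 30631576 to 30634296 for CRE111, on chromosome 1 at 80240739 to 80241617 for CRE18, on chromosome 6 at 100253881 to 100256209 for CRE132 and on chromosome 1 at 20808306 to 20810894 for CRE140. For Oct4DE it was an isolated fragment on chromosome 17 at 6269431 to 6273191. The viewpoint was there taken as the fragment with the most reads in the 1 Mb window with the most fragments, a step added after seeing the data, at 35652112 to 35659415. Within 100 kb of each chosen fragment lay a stretch of 14.5 to 33.7 kb in which none of the 3 libraries listed a fragment, and at CRE18 and Oct4DE it adjoined that fragment. For Oct4DE it reached from 35619816 to 35652111, and for CRE140 from 20842997 to 20876730. In the GRCm38 gene table, whose coordinates were not used, Pou5f1 is also on chromosome 17, between H2-Q10 and Tcf19. Lrrc31, set beforehand to be named with CRE111, is on chromosome 3 in that table, between Lrriq4 and Samd7. No gene was placed on the mm9 bins, so contacts are given by position.

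E14 and MEF libraries differed in where their reads lay. At all 5 viewpoints the MEF library had a larger share of its reads on the viewpoint chromosome than either E14 library. At CRE132 the share was 19.1% ± 3.70 (SD, n = 2) in E14 and 45.3% in MEF. At Oct4DE it was 6.98% ± 0.345 in E14 and 27.5% in MEF, at CRE140 19.4% ± 0.423 and 41.1%, at CRE18 16.1% ± 6.89 and 34.5%, and at CRE111 15.9% ± 4.10 and 23.9%. E14 spread its reads over more fragments, by 11.5 times at Oct4DE and by 4.70 times at CRE140.

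Over the 5 viewpoints, the share on the viewpoint chromosome was 19.0 percentage points higher in MEF, with E14 minus MEF at -18.97 ± 6.76 (SD over viewpoints). The exact two-sided sign-flip test gave p = 0.062 (2 of 32 sign patterns), the smallest p that 5 viewpoints allow, and a Benjamini-Hochberg value of 0.0885 over 17 such tests, so no measure tested over the viewpoints could pass 0.05. With each fragment counted once, the difference was -8.98 points (exact sign-flip p = 0.062). The Wilson 95% intervals of these shares reached at most 0.0976 points either side, which covers counting error only.

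**Figure D1:**
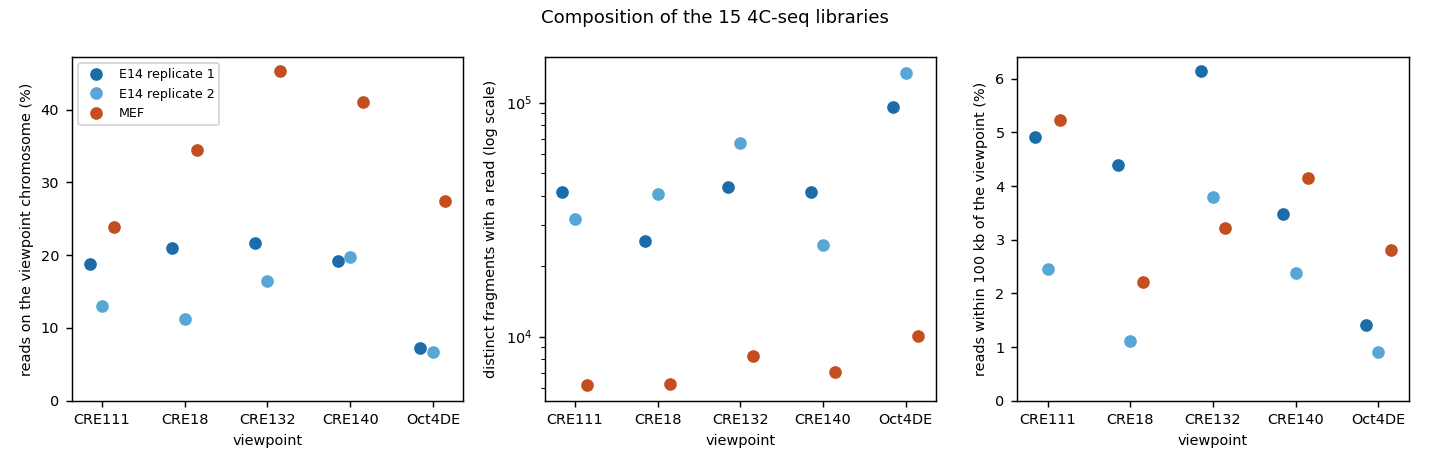
Each point is 1 library. The left and right panels give the percent of reads on the viewpoint chromosome and within 100 kb of the viewpoint fragment, and the middle panel the number of distinct fragments with a read, on a log axis. All 5 MEF libraries lie above both E14 libraries of their viewpoint in the left panel and, at 6205 to 10029 fragments, below all 10 E14 libraries in the middle panel.

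Nearer to the viewpoints the share of reads showed no common direction. The share of a library's distinct fragments that lay within 100 kb was lower in E14 at all 5 viewpoints, but E14 listed more fragments in all. The number of fragments within 1 Mb was higher in E14 at 5 of 5 viewpoints, by 196 on average. At CRE132, 4.97% ± 1.66 of E14 reads (n = 2) and 3.21% of MEF reads (Wilson 95% interval 3.19 to 3.24) lay within 100 kb, and both E14 libraries were above MEF. At CRE111, CRE140 and Oct4DE both E14 libraries were below MEF, with 3.68% ± 1.74 against 5.23%, 2.93% ± 0.787 against 4.15%, and 1.15% ± 0.356 against 2.81%. At CRE18 the E14 libraries lay on either side of MEF, at 4.39% and 1.11% against 2.22%. The mean difference over viewpoints was -0.43 points (exact sign-flip p = 0.625), and 0.54 without E14 replicate 2. With each fragment counted once it was -0.442 (exact sign-flip p = 0.062), and within 10 kb -0.0419, with E14 lower at 5 of 5 viewpoints in both. These are shares of all listed fragments, of which E14 had more at every viewpoint. They cannot show that E14 had fewer fragments near the viewpoint. The shares within 10 kb and 100 kb were not recomputed centred on the unlisted stretch near each viewpoint fragment, so their dependence on the chosen centre was not tested. Within 1 Mb the MEF share of reads was higher on average at every viewpoint, and E14 minus MEF was -3.79 points (exact sign-flip p = 0.062). Without E14 replicate 2 it was -1.95 (exact sign-flip p = 0.188), with E14 lower at 4 of 5 viewpoints, and without replicate 1 it was -5.63. At CRE18 the E14 libraries again lay on either side, at 9.14% and 2.30% against 7.65%.

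Reads fell with distance faster in both E14 libraries than in MEF at CRE132, Oct4DE, CRE18 and CRE140, over 10 kb to 1 Mb. The slope of log10 reads per kb against log10 distance, from 10 kb to 1 Mb, was -0.50 ± 0.0047 (n = 2) in E14 and 0.16 in MEF at CRE132. It was -0.80 ± 0.086 and -0.44 at Oct4DE, -0.86 ± 0.041 and -0.30 at CRE18, and -0.68 ± 0.0036 and -0.32 at CRE140. At CRE111 it was -0.41 ± 0.13 in E14 and -0.92 in MEF, but the MEF library had 0 reads in the nearest band, so its slope rested on 7 bands. Over those 7 bands, the E14 slopes of -0.97 and -0.77 lay on either side of MEF. The mean difference was -0.28 (exact sign-flip p = 0.25), and -0.38 over bands with reads in all 3 libraries (exact sign-flip p = 0.125), a fit chosen after seeing the data. From 20 kb to 2 Mb it was -0.29, with E14 lower on average at 5 of 5 viewpoints (exact sign-flip p = 0.062) but the E14 libraries on either side of MEF at CRE111 and CRE140. With each fragment counted once it turned to 0.26, above 0 at 5 of 5 viewpoints (exact sign-flip p = 0.062). The unlisted stretch near each viewpoint fragment gave no reads to the near bands it crossed, so the slopes depend in part on it. At CRE111 that stretch, 30612630 to 30627123, covered the nearest band on the side of lower coordinates. Slopes were not refitted without the stretch or centred on it, so its effect on them, including the 0.16 in MEF at CRE132, was not tested.

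Across 20 kb bins within 1 Mb, Spearman's rho was higher between the E14 libraries than between E14 and MEF at all 5 viewpoints. Between the E14 libraries it was 0.914 at CRE132, 0.90 at Oct4DE, 0.811 at CRE140, 0.756 at CRE111 and 0.724 at CRE18. Against MEF, the E14 libraries reached 0.733 and 0.755 at CRE132, 0.693 and 0.694 at Oct4DE, 0.513 and 0.579 at CRE140, 0.723 and 0.630 at CRE111, and 0.338 and 0.348 at CRE18. These are correlations across bins, which are not independent replicates. The mean excess of rho within E14 was 0.22 ± 0.11 (SD over viewpoints, exact sign-flip p = 0.062). It was also present when the MEF library was replaced by 100 substitutes drawn from the fragments of these E14 libraries, with its number of fragments and its read values, in 94 of the 100 at CRE18, 98 at CRE140 and 100 at the others. The MEF rho (mean over the E14 libraries) was 0.343 at CRE18 and 0.546 at CRE140, below all 100 substitutes (medians 0.645 and 0.71). At CRE111, CRE132 and Oct4DE it was 0.677, 0.744 and 0.693, at or above 75, 98 and 71 of the 100. The substitutes took their fragments from the libraries they were compared with, which can raise their rho. Their read values were placed at random, which can lower it. The place of MEF among them therefore does not tell a difference between the cell types from few fragments.

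Around CRE132, of 98 bins of 20 kb tested, 30 passed an adjusted p under 0.05 between E14 and MEF (edgeR quasi-likelihood test, Benjamini-Hochberg), 24 higher in E14 and 6 higher in MEF. With the 100 substitutes in place of the MEF library, a median of 37 bins passed (22 to 49), and 93 of the 100 gave at least 30. On chromosome 6, the longest run of adjacent tested bins called in 1 direction held 10 bins, from 100185046 to 100405045, on both sides of the viewpoint. It was picked after the values were seen, so the shared direction, higher in E14, was fixed by the choice. The log2 changes were 0.77 to 2.91. Of the 10, 8 were higher in E14 with all reads as the library size, 4 with reads limited to the 95th percentile and 3 with each fragment counted once. The highest E14 bin, at 100305046 to 100325045, chosen after the values were seen, held 110144 ± 4040 CPM in E14 (n = 2) and 34027 in MEF, a log2 change of 1.69 ± 0.12 (SE, adjusted p = 4.0e-06) that turned to -0.45 (adjusted p = 0.026) with reads so limited. Bins within 200 kb held 60.6% ± 0.253 of the bin reads in E14 and 37.2% in MEF (Wilson 95% interval 37.0 to 37.4).

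Farther from CRE132, bins changed both ways. The 5 largest changes towards E14 all fell in bins where MEF had 0 reads. They lay at 100625046 (the start of the bin), 100965046, 101045046, 99285046 and 101105046, between 380 and 960 kb from the viewpoint. The bin at 100625046 had 246 and 753 reads in the E14 libraries, at least 318-fold higher against a floor of 3 reads in the MEF library. It was at least 122-fold with E14 replicate 1 alone and 514-fold with replicate 2 alone. The others were at least 137-fold to 222-fold higher, and at least 49.2-fold to 295-fold with 1 E14 library alone. These bounds cover the counting of reads only, not fragments that the MEF library missed. The bin at 99365046 had 27 and 0 reads in E14 and 5030 in MEF, all on 2 fragments (log2 change -7.88 ± 1.24, adjusted p = 0.00081). MEF was 125-fold above E14 replicate 1 and at least 818-fold above replicate 2, and the call ended with DESeq2 (adjusted p = 0.15). The bin at 100545046, 300 kb away, was 10.9-fold higher in MEF (-3.45 ± 0.45, adjusted p = 0.00034), 8.18-fold and 16.4-fold against E14 replicates 1 and 2 alone, and that at 99845046 was 3.62-fold higher. Those at 100885046 (35.1-fold and 5.87-fold against replicates 1 and 2 alone) and 100805046 were 10.1-fold and 6.38-fold higher in MEF, but turned to log2 changes of 0.03 and 0.43 with each fragment counted once. Scaling by all reads of each library left 4 bins higher in E14 and 4 in MEF, with 0 of the 10 adjacent bins called. That scaling ended the calls at 99845046 (adjusted p = 0.060) and 99285046 (adjusted p = 0.052). A 2 Mb window called 0 bins with edgeR (63 of 191 at an unadjusted p under 0.05). Reads limited to the 95th percentile ended the calls of these 5 bins towards MEF except that at 99845046 (adjusted p of 0.095 to 0.31), and of the bin at 99285046 (adjusted p = 0.076). The call at 100885046 also ended with the total in the tested bins (adjusted p = 0.051), touching fragments kept once (0.082) and fragments of at least 2 reads (0.077). With each fragment counted once edgeR called 0 bins (1 at an unadjusted p under 0.05).

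At Oct4DE, 45 of 96 bins passed, 33 higher in E14 and 12 higher in MEF, against a median of 36 (20 to 58) in the 100 substitutes, of which 7 gave at least 45. The bin next to the viewpoint on chromosome 17, at 35665764 to 35685763, was the highest in E14, with 150680 ± 32491 CPM (n = 2) against 42000 in MEF (log2 change 1.84 ± 0.21, adjusted p = 0.0018), but -0.85 (adjusted p = 0.85) with each fragment counted once and -0.67 (adjusted p = 0.0042) with reads limited to the 95th percentile. The highest MEF bin was another, at 35465764 to 35485763 and 180 kb away, with 77539 in MEF and 17224 ± 1196 in E14 (log2 change -2.17 ± 0.21, adjusted p = 0.0012). Both bins were chosen for their height after the values were seen. MEF had 0 reads in 21 of the called bins.

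The 5 largest changes towards E14 at Oct4DE were bins with 0 MEF reads at 35305764, 36145764, 35105764, 36485764 and 35345764. The first had 211 and 275 reads in E14 and was at least 335-fold higher, and the others were at least 163-fold to 297-fold higher. The last of these was at least 92.0-fold with E14 replicate 2 alone. Here too the bounds do not cover fragments missed in MEF, which had a median of 1 distinct fragment per bin. Towards MEF, the bin at 36285764 had 0 reads in both E14 libraries and 201 in MEF, at least 16.4-fold higher against 3 reads per E14 library, and all on 1 fragment. The bin at 35085764 was 6.17-fold higher in MEF (log2 change -2.63, adjusted p = 0.048), 13.6-fold and 3.99-fold against E14 replicates 1 and 2 alone, and its call ended with no filter on low bins (adjusted p = 0.052). Those at 36465764, 34705764 and 35405764 were 8.01-fold, 6.06-fold and 5.14-fold higher in MEF (-3.00, -2.60 and -2.36), but turned to 0.58, 0.13 and 0.14 with each fragment counted once. Scaling by all reads of each library gave 31 bins higher in E14 and 36 in MEF, moved the median log2 change by -1.79 and left the bin at 35665764 at 0.09 (adjusted p = 0.95). A 2 Mb window ended 4 of these 5 calls towards MEF, all but that at 36465764 (adjusted p of 0.072 to 0.11). Counting each fragment once called 0 bins with edgeR (4 at an unadjusted p under 0.05).

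At CRE140, 7 of 91 bins passed, 5 higher in E14 and 2 higher in MEF, against at most 4 in the 100 substitutes. On chromosome 1, the bin at 20659601 to 20679600, 140 kb from the viewpoint, had 3775 and 1745 reads in E14 and 0 in MEF, at least 720-fold higher (adjusted p = 0.023). The adjacent bins at 20439601 and 20459601 and the bin at 21059601 also had 0 MEF reads and were at least 485-fold, 341-fold and 440-fold higher, the first at least 274-fold with E14 replicate 1 alone. The bin at 21319601 had 1628 and 2549 reads in E14 and 1 in MEF, a ratio of 1882 (counting interval 338 to 74325), and 1068 with E14 replicate 1 alone. Its neighbour at 21299601 was 7.72-fold higher in MEF (log2 change -2.95 ± 0.73, adjusted p = 0.049; 0.19 with each fragment counted once), and the bin at 20019601 was 208-fold higher in MEF on 2 fragments (372-fold against E14 replicate 1 alone). MEF had 0 reads in 34 of the 91 bins, and the median log2 change over all of them was 3.02. A bin held a median of 1 distinct MEF fragment, and the lower bounds above do not cover fragments missed in MEF. Size factors of DESeq2, or the total in the tested bins, gave 5 bins higher in E14 and 1 in MEF. The call at 21299601 also ended with a 2 Mb window (adjusted p = 0.24) and with reads limited to the 95th percentile (adjusted p = 0.12). With edgeR, 0 bins were called when each fragment was counted once, when fragments with 1 read were left out and in a 500 kb window (10, 26 and 14 at an unadjusted p under 0.05), and DESeq2 called 39 with the settings used throughout.

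At CRE111 and CRE18 no bin passed the adjusted threshold with edgeR. At CRE111, 14 of 98 bins had an unadjusted p under 0.05, 12 of them higher in E14, and the smallest adjusted p was 0.28. The DESeq2 Wald test called 36, 28 of them higher in E14. The highest bin in both cell types was the same, at 30602937 to 30622936 on chromosome 3, with 122931 ± 41910 CPM in E14 (n = 2) and 145111 in MEF (log2 change -0.24 ± 0.39). At CRE18, 27 of 98 bins had an unadjusted p under 0.05, 20 of them higher in E14, and DESeq2 called 39, 28 of them higher in E14. The bin at 80251179 to 80271178 on chromosome 1 held 127170 ± 7985 in E14 and 21180 in MEF (log2 change 2.59 ± 0.24, adjusted p = 0.055). The bin at 79431179, 800 kb away, held 4936 ± 494 in E14 and 53048 in MEF (log2 change -3.43 ± 0.51, adjusted p = 0.063). The CRE18 result lay at the threshold, since DESeq2's size factors in edgeR called 6 bins higher in E14 and 4 in MEF, these 2 bins among them. These bins of CRE111 and CRE18 were chosen after the values were seen.

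**Figure D2:**
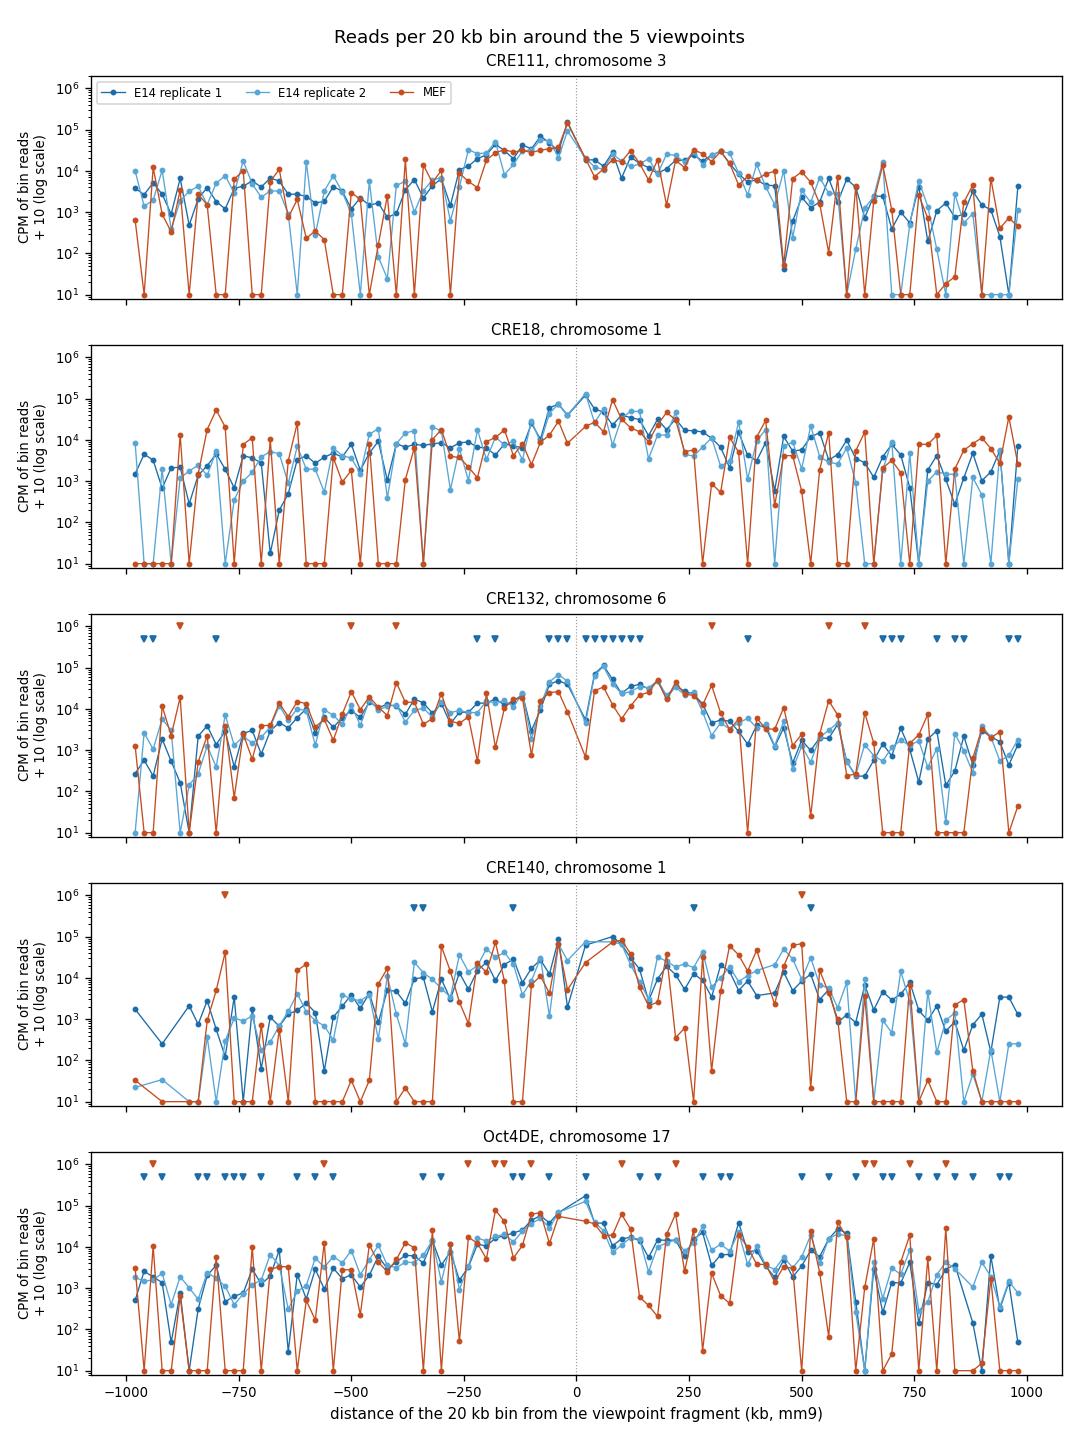
Each panel shows 1 viewpoint, with the distance of each tested 20 kb bin from the viewpoint fragment on the x axis and TMM-normalised CPM of bin reads plus 10 on a log y axis. Lines are the 2 E14 libraries and the MEF library, and triangles mark bins called higher in E14 (blue, lower row) or in MEF (orange, upper row). CRE132 has 10 adjacent bins called higher in E14 around the viewpoint (0 of them with all reads as the library size). They were picked after the values were seen, as the longest such run. Points on the floor of the MEF line are bins with 0 reads.

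With 1 MEF library per viewpoint, that library was assumed to vary like the E14 libraries, and the biological coefficient of variation was 0.52 at Oct4DE and CRE132 and 0.93 to 1.02 at the others. In counts simulated at these values, which leave out the small number of MEF fragments, 16-fold changes were called in 62.0% of changed bins for the CRE132 comparison, 55.3% for Oct4DE, 4.40% for CRE111, 3.40% for CRE18 and 1.71% for CRE140.

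On the viewpoint chromosome, fragments the authors' caller put below a q-value of 0.05 were fewer in MEF than in either E14 library at all 5 viewpoints. MEF also listed fewer fragments there, 1104 to 1695 against 2763 to 6375 in the E14 libraries. The counts below are not set against these numbers, so they do not show that a smaller part of the MEF fragments was called. Over the 5 viewpoints, 95 fragments were called in E14 replicate 1, 96 in replicate 2 and 54 in MEF. Of these, 63 were called in both E14 libraries, 52 of them within 100 kb of the viewpoint, and 18 were called in all 3 libraries. No distance was left out of these counts, so calls within 10 kb of the viewpoint fragment are included. The viewpoint was placed at the fragment with the most reads, so calls near it follow in part from that placement. The q-values are the authors' and were computed per library. CRE132 had the most fragments called in both E14 libraries, 18, and 6 of them were also called in MEF. At CRE18, 9 were called in both E14 libraries and 1 in all 3, at CRE140 14 and 3, at Oct4DE 13 and 2, and at CRE111 9 and 6. All 9 at CRE111, 9 at CRE18 and 18 at CRE132 had at least 1 read in MEF, as did 10 of 14 at CRE140 and 12 of 13 at Oct4DE. The log2 ratio of called cis fragments, E14 over MEF, averaged 0.75 ± 0.68 (SD over viewpoints) and was above 0 at 5 of 5 viewpoints (exact sign-flip p = 0.062). On other chromosomes it averaged 1.07 ± 1.76 (exact sign-flip p = 0.188), 0.18 without E14 replicate 2 and 1.53 without replicate 1. Both E14 libraries were above MEF at CRE111 and CRE18 and below it at Oct4DE (59 and 53 fragments against 149), and they lay on either side at CRE132 (45 and 96 against 65) and CRE140.

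The fragments named next lie outside 10 kb of the viewpoint fragment, which was itself placed by its reads. Except at Oct4DE, the fragments with the smallest q in both E14 libraries lay close to the viewpoints. At CRE111 it was 30604285 to 30607042, 27.3 kb from the viewpoint fragment, with 3683 ± 2793 CPM of the library in E14 (n = 2) and 5311 in MEF, where it was also called (q = 3.5e-25). At CRE18 it was 80249977 to 80257141, 12.4 kb away, with 2339 ± 1292 in E14 and 677 in MEF, where it was not called (q = 1.0). At CRE132 it was 100295264 to 100296910, 41.0 kb away, with 3660 ± 1522 in E14 and 3416 in MEF, and it was called in both. At CRE140 it was 20818983 to 20822553, 11.2 kb away, with 1651 ± 207 in E14 and 1279 in MEF, where it was not called. A CRE140 fragment 82.2 kb away, at 20891158 to 20892478, had 1543 ± 105 in E14 and no listed read in MEF. Its neighbour at 20886181 to 20891065 had 1829 ± 1071 in E14 and 2349 in MEF. The bin holding both, at 20879601, was not called with edgeR (log2 change 0.24, adjusted p = 0.61). The CRE140 fragment at 20824729 to 20826316 had 1699 ± 679 in E14 and no listed read in MEF. That at 20906442 to 20907910 had 1472 ± 276 in E14 and 4144 in MEF. At Oct4DE, the fragment at 35671798 to 35674741, 17.5 kb away, had 1449 ± 541 in E14 and 1573 in MEF. A smaller q belonged to a fragment at 6269431 to 6273191 on the same chromosome, with 2853 ± 1282 in E14 and 211 in MEF. It was the only one of the 63 beyond 1 Mb. The farthest of the others lay 296 kb from the viewpoint at CRE111, 264 kb at CRE140, 225 kb at CRE132 and 131 kb at CRE18.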

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

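The tests of carry-over and of a second priming site, the stretch they use and the slope over shared bands were chosen after the result was seen. In the Oct4DE libraries, whose viewpoint was placed on chromosome 17, 500 kb of chromosome 14 (97500000 to 98000000, mm9) held a cluster of reads. The stretch held 2.05% ± 0.294 of the reads in E14 (SD, n = 2), on 158 and 155 fragments, and 0.388% in MEF (Wilson 95% interval 0.380 to 0.396), on 18 fragments. In the 12 libraries of the other viewpoints it held at most 0.0972%. Of the 45 fragments on other chromosomes called by the authors' q in both Oct4DE E14 libraries, 32 were on chromosome 14, and none of these 32 was called in MEF. The 32 include fragments outside the stretch, starting at 97457767, 97465905, 101136227 and 101141243.

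Carry-over from the other viewpoints' libraries is argued against by their highest share, 0.0972%, below the lowest Oct4DE share. Carry-over from a library outside this series is not excluded. A candidate explanation is that the Oct4DE primers also read from a second site. From 10 to 250 kb around the top fragment, 97571936 to 97573667, the slope of reads with distance was -0.66 and -0.79 in the E14 libraries and 1.497 in MEF, while 45.5%, 45.8% and 66.9% of the stretch's reads lay within 10 kb of that fragment. With 18 MEF fragments in the stretch, 4 of them within those 10 kb, a second priming site, a contact and any other difference between the cell types cannot be told apart here.

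In 4 measures the difference between E14 and MEF had opposite signs at different viewpoints as first computed, and these differences between viewpoints were not tested. E14 minus MEF in the percent of reads within 10 kb was 0.828 at CRE132, with both E14 libraries above MEF, and below 0 in both at CRE111, CRE140 and Oct4DE. Within 100 kb it was 1.76 at CRE132 and again below 0 in both at those 3 viewpoints. As shares of all distinct fragments, both were lower in E14 at 5 of 5 viewpoints. E14 listed more fragments in all, so this does not bear on the opposite sign at CRE132. The slope of reads with distance was 0.52 higher in E14 at CRE111 and lower in both E14 libraries at the other 4 viewpoints, but this value set 8 bands in E14 against 7 in MEF. Over the same 7 bands it was 0.05, with the E14 libraries on either side of MEF. Neither the slopes nor the shares by distance were recomputed centred on the unlisted stretch near each viewpoint fragment. The log2 ratio of fragments called on other chromosomes was -1.40 at Oct4DE, with both E14 libraries below MEF, and above 0 in both at CRE111 and CRE18.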

How the results depend on the processing

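The alternatives that keep touching fragments of equal count once, leave out fragments with 1 read in the bins, centre bins on the unlisted stretch, use the first viewpoint rule or fit slopes over bands with reads in all 3 libraries were chosen after seeing the data. Within a viewpoint no paired analysis was possible, because there was 1 MEF library, whose title carries no replicate number. The sign-flip tests paired E14 and MEF by viewpoint. The count of called bins moved by over 1.5 times as follows, and the cause was not tested unless stated. From 0 at CRE111 it went to 36 with the DESeq2 Wald test, 9 with a 2 Mb window, 3 with a 500 kb window, 8 with 50 kb left out, 5 with reads limited to the 95th percentile and 7 with fragments of at least 2 reads. From 0 at CRE18 it went to 39 with DESeq2, 10 with DESeq2's size factors in edgeR, 13 with the total in the tested bins, 25 with 10 kb bins, 10 with 50 kb bins, 1 with a 2 Mb window, 6 with a 500 kb window, 12 with 50 kb left out, 10 with limited reads and 17 with touching fragments kept once. From 30 at CRE132 it went to 8 with all reads as the library size, 73 with 10 kb bins, 10 with 50 kb bins, 0 with a 2 Mb window (63 bins at an unadjusted p under 0.05), 17 with a 500 kb window (fewer bins) and 0 with each fragment counted once. From 7 at CRE140 it went to 39 with DESeq2, 20 with all reads, 28 and 14 with 10 kb and 50 kb bins, 12 and 0 with 2 Mb and 500 kb windows (14 at an unadjusted p under 0.05 in the latter), 19 with 50 kb left out, 12 with E14 thinned, 17 with touching fragments kept once, 0 with fragments of at least 2 reads (26 at an unadjusted p under 0.05) and 0 with each fragment counted once. From 45 at Oct4DE it went to 86 and 12 with 10 kb and 50 kb bins, 23 with a 500 kb window, 70 with limited reads, 0 with each fragment counted once and 2 with the first viewpoint rule. DESeq2 called 45 at CRE132 and 53 at Oct4DE. Centring on the unlisted stretch moved no count by over 1.5 times. Only the bin calls were rerun with that centre, not the slopes or the shares of reads by distance.

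A bin held a median of 3 to 5 distinct fragments in E14 libraries and 1 to 3 in MEF, so a test on distinct fragments has little to work with. Its variance estimates were mostly 0 at CRE132 and Oct4DE, and it had 9, 8, 1, 10 and 4 bins at an unadjusted p under 0.05 (CRE111, CRE18, CRE132, CRE140, Oct4DE). It turned 6 of the 27 named bins, all called higher in MEF, to log2 changes above 0: 0.43 and 0.028 at CRE132 (100805046, 100885046), 0.19 at CRE140 (21299601), and 0.13, 0.14 and 0.58 at Oct4DE (34705764, 35405764, 36465764). In all other alternatives run on the same bins no named bin changed direction. Without E14 replicate 1 or 2, values with no test, all 27 kept theirs. The choice of bins made this so, as named bins have both E14 libraries on the same side of MEF. Bins of 10 and 50 kb do not hold the named bins. Relative to TMM, all reads as the library size moved the median log2 change by -0.51 at CRE111, -0.60 at CRE18, -0.85 at CRE132, -0.22 at CRE140 and -1.79 at Oct4DE.

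Over the viewpoints, the difference within 100 kb ran from -1.40 to 0.54 when each E14 replicate was left out, that within 1 Mb from -5.63 to -1.95, and the log2 ratio of called fragments on other chromosomes from 0.18 to 1.53. The slope difference turned to 0.26 with each fragment counted once. Called cis fragments shared by all 3 libraries rose from 18 to 39 when calls within 10 kb counted as shared. The mean slope difference was -0.38 over bands with reads in all 3 libraries. The means of the measures over viewpoints other than the share within 100 kb and the slope kept their direction in every alternative run, but a p of 0.062 cannot show stability. The planned gene-list test, with its alternatives, was not run.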

Other observations

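The tests of few fragments and of read depth at called bins, and of fragments with 1 read, were chosen after the results were seen. That counting each fragment once calls 0 bins was also known before the first of these was set. Fragments on other chromosomes that the authors' q called in both E14 libraries were few, 67 over the 5 viewpoints, and 17 of them were also called in MEF. Touching fragments with equal counts were counted separately, so these are not numbers of sites. Whether the fragments are contacts was not tested. CRE132 had 10 of the 67, and 6 of these 10 were called in all 3 libraries. They formed 3 pairs of touching fragments with equal or nearly equal counts, on chromosome 13 at 26455572 to 26467113 and at 93035618 to 93040588 and on chromosome X at 123521170 to 123526638. The first fragment of the chromosome X pair held 1136 ± 51.7 CPM in E14 (SD, n = 2) and 987 in MEF. At Oct4DE, 10 of the 13 such fragments outside chromosome 14 were also called in MEF. The highest, on chromosome 8 at 85649702 to 85650116, held 6063 ± 364 in E14 and 4272 in MEF, above any Oct4DE fragment named within 1 Mb. A fragment on chromosome 1 at 24620281 to 24623682 was the only 1 called in both E14 libraries of more than 1 viewpoint, CRE132 and Oct4DE. It held 224 ± 108 in E14 and no listed read in MEF at CRE132, and 305 ± 104 in E14 and 2798 in MEF at Oct4DE.

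Bins called between E14 and MEF may come from the few distinct fragments of the MEF libraries. To test this, 100 substitutes for the MEF library were drawn from the E14 fragments, with the number of fragments and the read values of the MEF library. At CRE132, 93 of the 100 draws gave at least the 30 called bins observed (median 37), and at Oct4DE 7 of the 100 gave at least 45 (median 36, 95th percentile 45.05). At CRE140 none gave the 7 observed (0 of 100, highest 4). The draws put the read values on fragments at random. In Spearman's rho with E14, MEF was at or above 98 of the 100 substitutes at CRE132, 71 at Oct4DE and 0 at CRE140. At CRE132 and Oct4DE the draws may thus call more bins than few fragments alone would. They rest on an assumed model and decide the question at no viewpoint. The rule set for them could not have excluded few fragments, as it also asked for a call with each fragment counted once. More reads in E14 is argued against, since E14 held 0.672 times the MEF reads in the bins at CRE132 and 0.236 times at Oct4DE, and at CRE140, where the ratio was 1.125, thinning E14 left 12 calls. A difference between the cell types stays open and untested apart from this.

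A hypothesis that MEF fragments with 1 read are carry-over from the E14 libraries of the same viewpoint found no clear answer. Fragments on other chromosomes with 1 MEF read were listed in those E14 libraries more often than fragments with at least 10 reads at 3 of 5 viewpoints. The mean difference was 0.0952 percentage points ± 15.0 (SD over viewpoints, exact sign-flip p = 1.0), from -23.5 at CRE111 to 13.0 at CRE132.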
